A study of Triticum urartu with 18 samples.

How the data were processed

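RNA-Seq was carried out on endosperm of Triticum urartu (the wild diploid wheat that gave the A genome of bread wheat, 1 untreated accession) at 5, 10, 15, 20 and 25 days post anthesis (DPA) and on flag leaf at 10 DPA. Per the labels, each of the 6 groups had 3 independent biological replicates, and embryo, aleurone, seed coat and pericarp were removed from the endosperm before total RNA was extracted with Trizol. The sequencing was on an Illumina HiSeq, and every sample description names the same lane, so no sequencing batch could be compared. The leaf titles carry an added suffix that the endosperm titles lack. Its meaning is not given, so a difference in handling between the tissues could not be checked.

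The authors' deposited table gives 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for each of 27121 genes in each of 18 libraries. Bowtie 0.12.2 is the only tool named in the submitters' processing notes. The genome build, the annotation and the program that counted the reads are not given in the sources used here. The table annotates 1160 genes: storage proteins, starch synthesis related genes, transcription factor families and individually named regulators. The other 25961 genes carry an identifier only, 0 identifiers matched the reference table of gene symbols, and chromosome positions were not used here. The column headings tie each column to a group and not to a sample within it, so library numbers are column numbers in the table. In 43 profiles, 115 genes hold values identical to those of another gene, so reads shared between related genes cannot be separated.

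Depth per library is not given in the files. A relative depth was estimated from the smallest FPKM steps of weakly detected genes and ran from 0.314 (leaf library 1) to 1.06 (10 DPA library 2) of that of 10 DPA library 1. No counting interval or detection limit was computed, since FPKM values do not give counts. A gene at 0 is described as listed at 0.

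Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on mean expression. Genes with an FPKM of at least 1 in at least 3 libraries of the fit were tested: 19418 genes in the fit of the 15 endosperm libraries, and 16709 in the fit of 6 libraries for endosperm against flag leaf. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 and its log2 change was at least 1 in size. The contrasts were 10 against 5 DPA, 15 against 10, 20 against 15, 25 against 20, 25 against 5, and endosperm against flag leaf at 10 DPA. An F-test over the 5 stages used the same endosperm fit. Each log2 change is given with the standard error (SE) of the fit, and each mean with its standard deviation (SD) over 3 libraries.

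The groups differ in how much of the total FPKM a few genes take, so each contrast was also fitted after median-ratio scaling. This sets the median ratio of genes above 0 in all libraries of the fit to a common value. These scaled counts stand beside those from the values as deposited.

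Gene lists were fixed before the data were examined, as search patterns over gene descriptions. Of the 25 fixed lists, 7 had members in the annotation: storage prolamins and the MYB, bZIP, Dof, NF-Y, MADS and WRKY families. The remaining lists had no members and are void. These covered 11S globulins, grain albumins and inhibitors, starch synthesis, sucrose entry, protein folding in the endoplasmic reticulum, cell cycle, histones, ribosomal proteins, photosynthesis, cell wall, late embryogenesis and desiccation, heat shock proteins, redox enzymes, proteases, markers of aleurone and embryo, markers of seed coat and pericarp, and the NAC and B3 families. The table's own classes, among them the starch synthesis related genes and the NAC, B3 and HSF families, were taken in after the table was seen. In all, 33 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 196 tests of list and contrast. With a correlation estimated from the data, 0 of the 196 tests had an adjusted p under 0.05.

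Named genes follow a rule fixed before the data were examined, extended to the starch synthesis, NAC and B3 classes after the table was seen. For each contrast these were the 10 largest rises and the 10 largest falls among called, annotated genes with a mean of at least 10 FPKM in the higher group and no overlap between the groups' libraries, and up to 3 members of each list with the highest mean. Shares of total FPKM were compared across the 5 stages by an exact permutation test of the one-way F statistic (upper tail) over all 1401400 partitions of the 15 libraries. The smallest p it allows is 7.1e-07, and 8 share measures were adjusted together. An exact test of 3 against 3 libraries cannot go below 0.1.

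The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at an FPKM of 5, median-ratio and total FPKM scaling, 1 fit of all 18 libraries, an estimated correlation, and leaving out each library in turn. Added after seeing the data were fits of the compared groups alone, scaling to the total outside the 12 most abundant genes, and a fit without the 20 DPA libraries and 25 DPA library 1. The 12 most abundant genes are those with the highest FPKM in any 1 library, and need not lead at every stage. The calls were tested on simulated data with the same spread, in which few genes were changed. Of 50 genes given a log2 change of 3 between 10 and 5 DPA, 30% were called, and of 50 given -1.5, 2% were called. In the real comparison 9460 of 19418 genes were called, which makes the adjusted p threshold less strict than in the simulation. The simulated shares therefore do not measure how many real changes were missed. Uncalled genes are still not shown to be unchanged. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.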

Results

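The series followed the transcripts of Triticum urartu endosperm through grain filling. It holds 18 RNA-Seq libraries, 3 from endosperm at each of 5, 10, 15, 20 and 25 days post anthesis (DPA) and 3 from flag leaf at 10 DPA. The total FPKM ran from 1300333 in 5 DPA library 1 to 3605504 in 25 DPA library 1, and read depth is unknown. At 5 DPA, 21372 to 21594 genes were above 0 per library, against 9328 to 11010 at 20 DPA. The 25 DPA libraries held 10644, 17135 and 17237 such genes.

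Storage prolamins, the gliadins and glutenins that make up most of the protein reserve of the wheat grain, took 0.00778% ± 0.00491 of the total FPKM at 5 DPA (SD, n = 3). Their share was 17.5% ± 0.444 at 10 DPA and 21.1% ± 0.848 at 15 DPA. At 20 DPA it was 1.03% ± 0.219, and the 25 DPA libraries gave 0.382%, 12.1% and 1.99%. The share differed across the stages (exact permutation p = 2.2e-05, adjusted p = 4.4e-05 over 8 measures). Gliadins made up 12.7% and 15.0% of the total at 10 and 15 DPA, low molecular weight glutenins 3.85% and 4.74%, and high molecular weight glutenins 0.941% and 1.41%. The 28 starch synthesis related genes took 0.268% ± 0.0114 at 5 DPA, 0.307% ± 0.0296 at 10 DPA, 0.0953% ± 0.0111 at 15 DPA and 0.00136% ± 0.000262 at 20 DPA (SD, n = 3), and 0.00411%, 0.0536% and 0.0182% in the 25 DPA libraries. Their share also differed across the stages, with an exact permutation p of 7.1e-07, the smallest that the partitions can give.

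A set of 12 unannotated genes, led by TRIUR3_32831 and TRIUR3_00135, was chosen after their values were seen, as those with the highest FPKM in any 1 library. They took 27.3% ± 4.35 of the total at 5 DPA, 46.5% ± 0.699 at 10 DPA, 53.8% ± 0.834 at 15 DPA and 84.6% ± 1.45 at 20 DPA (SD, n = 3). In the 25 DPA libraries their share was 85.4%, 44.5% and 45.7%, and in the leaf libraries it was 67.9%, 43.4% and 39.9%. Among the 12, TRIUR3_00136 and TRIUR3_00018 held identical values, and each is counted in these shares. Of the FPKM outside these 12 genes, the prolamins took 32.8% ± 0.439 at 10 DPA, 45.7% ± 1.35 at 15 DPA and 6.69% ± 1.45 at 20 DPA. In the 25 DPA libraries they took 2.62%, 21.9% and 3.67%, so library 2 lay above the 20 DPA libraries and the other two below them. That share differed across the stages as well (exact permutation p = 4.1e-05). It is not free of other abundant genes. At 20 DPA the 20 most abundant genes of each library took 94.8% ± 0.343 of the total (SD, n = 3), against 84.6% for the 12.

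**Figure D1:**
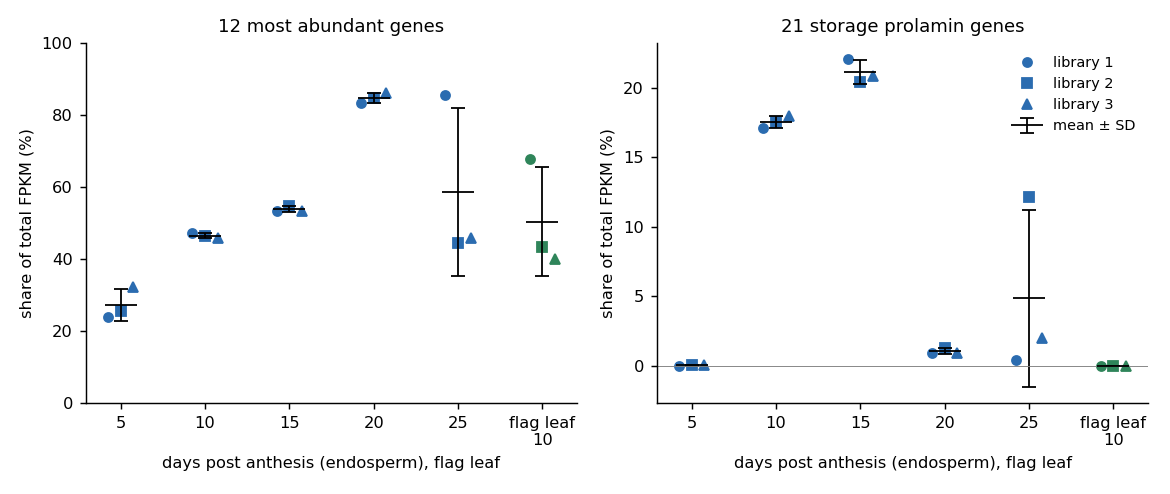
Share of total FPKM (%, linear axes from 0) of the 12 genes with the highest FPKM in any 1 library and of the 21 storage prolamin genes, with 1 point per library and bars for mean ± SD of 3 libraries. The 12 genes reach 83.2% to 86.1% at 20 DPA and 85.4% in 25 DPA library 1, while the prolamins stand at 17.5% and 21.1% at 10 and 15 DPA.

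The comparison of 10 with 5 DPA asked which transcripts change as the grain enters filling. Every one of the 21 storage prolamin genes rose, 21 of 21 also when adjusted over the list alone, with a median log2 change of 11.51 against -1.23 for all genes tested. The gliadin gene Gli-γ-1 went from 10.1 ± 1.71 to 52897 ± 375 FPKM (SD, n = 3), a log2 change of 12.22 (SE 0.76, adjusted p = 1.93e-08). The low molecular weight glutenin gene TuA3-538a went from 17.5 ± 13.6 to 26605 ± 1028 FPKM. TuGBSSI, the granule-bound starch synthase that makes amylose, rose from 55.9 ± 14.4 to 1008 ± 205 FPKM, a log2 change of 4.16 (SE 0.87, adjusted p = 0.00125). TuSuSy2, a sucrose synthase, rose from 296 ± 11.3 to 1731 ± 27.5 FPKM.

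Among regulators, TuWPBF (TRIUR3_33098), a Dof factor that binds the prolamin box of storage protein promoters, rose from 12.1 ± 2.54 to 127 ± 10.6 FPKM (SD, n = 3), a log2 change of 3.30 (SE 0.62, limma adjusted p = 0.000539). The NF-YC gene TRIUR3_29815 rose from 25.0 ± 11 to 449 ± 9.02 FPKM. The NAC gene TRIUR3_00447 rose from 0.79 ± 0.816 to 198 ± 33.6 FPKM, a log2 change of 6.89 (SE 0.95), and 2 further NAC genes, TRIUR3_01582 and TRIUR3_25136, rose by 6.35 and 7.04. In the other direction, the B3 gene TRIUR3_02309 fell from 330 ± 84.7 to 9.85 ± 2.72 FPKM, and the HD-ZIP gene TRIUR3_12807 fell from 89.7 ± 13.3 to 3.61 ± 0.617. The MADS-box gene TRIUR3_28216 fell from 732 ± 43.3 to 146 ± 14.6 FPKM, a call that was lost after median-ratio scaling (log2 change -1.06).

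Of 28 starch synthesis related genes, 7 rose and 10 fell between 5 and 10 DPA, and 7 and 10 when adjusted over the list alone. Their median log2 change was -0.73 and their mean -0.19, whereas camera placed them above other genes (adjusted p = 0.00397), with a median 0.50 over that of all genes. That call was lost at adjusted p = 0.998 with an estimated correlation. For the prolamins camera gave an adjusted p of 1.07e-69, and adjusted p = 0.109 with an estimated correlation. Of 31 MADS-box genes 22 fell and 0 rose (0 at an unadjusted p under 0.05), and 24 fell when adjusted over the list alone. Their fall relative to other genes had a camera adjusted p of 0.0101, and adjusted p = 0.998 with an estimated correlation. Without 5 DPA library 2 or 3, 13 or 14 of the MADS-box genes were called. In the same comparison, the median of 83 genes abundant in flag leaf (at least 1000 FPKM there and 10 times their 15 DPA mean, and above 0 in 5 DPA library 1) went from 529, 474 and 482 FPKM in the 5 DPA libraries to 128, 103 and 99.9 in those of 10 DPA. Over all genes 9460 were called, 613 higher and 8847 lower, and 6239 without 5 DPA library 1. After median-ratio scaling 2233 were called, 930 higher and 1303 lower, among them all 21 prolamin genes, 9 starch genes higher and 4 lower, and 10 MADS-box genes lower.

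The comparison of 15 with 10 DPA asked what changes in the middle of grain filling, and the largest falls among annotated genes included a sucrose synthase, a starch synthase and Tuglup3. TuSuSy2 fell from 1731 ± 27.5 to 67.7 ± 24.5 FPKM (SD, n = 3), a log2 change of -4.73 (SE 0.48, limma adjusted p = 5.83e-06). TuSSIIa, a starch synthase that builds amylopectin, fell from 197 ± 17.8 to 7.97 ± 3.66 FPKM. Tuglup3 (TRIUR3_18628), whose rice namesake encodes the vacuolar processing enzyme that matures storage proteins, fell from 1034 ± 21.1 to 38.9 ± 10.7 FPKM, a log2 change of -4.74 (SE 0.66). The WRKY gene TRIUR3_26868 fell from 20.9 ± 0.327 to 0.307 ± 0.531 FPKM. In the other direction, TRIUR3_19198, a heat shock factor (HSF) gene, rose from 0.467 ± 0.306 to 11.5 ± 3.29 FPKM, a log2 change of 3.08 (SE 0.79, limma adjusted p = 0.0128). It was not called without 15 DPA library 3 or with a pseudocount of 5.

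Prolamin transcripts stayed abundant at 15 DPA: limma called 0 of 21, with 0 at an unadjusted p under 0.05, 0 when adjusted over the list alone, and 0 after median-ratio scaling. Gli-γ-1 stood at 91495 ± 7616 FPKM against 52897 ± 375 at 10 DPA (SD, n = 3). The limma SE pools the spread of all stages, with the unlike 25 DPA libraries, so uncalled prolamins are not shown to be unchanged. Some had libraries that did not overlap, in either direction. Gli-γ-1 had 52671 to 53330 FPKM at 10 DPA and 84596 to 99667 at 15 DPA, and Gli-α-5 10534 to 11161 and 7043 to 9508. The median log2 change of the prolamins was 0.34, which lay 1.00 above that of all genes (camera adjusted p = 0.00033, and adjusted p = 0.998 with an estimated correlation). Of the 28 starch genes 11 fell and 0 rose (0 at an unadjusted p under 0.05), and 12 fell when adjusted over the list alone, although camera gave no call (adjusted p = 0.117). Leaving out any 1 of the 6 compared libraries left 6 or 7 of these calls, and median-ratio scaling left 4. TuSBEI, a starch branching enzyme, stood at 791 ± 50.5 against 555 ± 108 FPKM, and TuGBSSI at 381 ± 72.5 against 1008 ± 205. Neither was called, although for each gene the 10 and 15 DPA libraries did not overlap. TuWPBF (TRIUR3_33098) stood at 37.4 ± 6.30 against 127 ± 10.6 FPKM, with a limma adjusted p of 0.0608, and was called without any 1 of the 25 DPA libraries. The whole comparison gave 3484 calls, 248 higher and 3236 lower, with a median log2 change over all genes of -0.65. It gave 1930 after median-ratio scaling (624 higher and 1306 lower), 6271 with the compared groups fitted alone, and 6502 without 25 DPA library 1.

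At 20 against 15 DPA, the question was what changes late in filling. TuGBSSI fell from 381 ± 72.5 to 0.253 ± 0.439 FPKM (SD, n = 3), a log2 change of -8.29 (SE 0.87, limma adjusted p = 3.81e-05). TuSBEI fell from 791 ± 50.5 to 19.8 ± 2.90 FPKM, and TuUGPase, a UDP-glucose pyrophosphorylase, from 97.7 ± 10.9 to 2.48 ± 1.79. TuWPBF (TRIUR3_33098) fell from 37.4 ± 6.30 to 0.32 ± 0.554 FPKM, a log2 change of -4.92 (SE 0.62). These 4 genes were also called lower after median-ratio scaling, with log2 changes of -7.65, -2.45, -2.81 and -4.06.

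All 21 prolamin genes were called lower at 20 DPA as deposited, 21 also when adjusted over the list alone, with a median log2 change of -3.76 against -1.09 for all genes. Gli-γ-1 went from 91495 ± 7616 to 9143 ± 2119 FPKM (SD, n = 3), a log2 change of -3.34 (SE 0.76, limma adjusted p = 0.00441). After median-ratio scaling 0 of 21 were called by limma, and the log2 change of Gli-γ-1 was -0.48. Camera placed the prolamins below other genes at an adjusted p of 2.11e-05, and adjusted p = 0.998 with an estimated correlation. Of the 28 starch genes 23 fell, 25 when adjusted over the list alone and 16 after median-ratio scaling. Camera gave an adjusted p of 4.79e-09 for them, and adjusted p = 0.998 with an estimated correlation. TuGAMYB (TRIUR3_27104), named after the gibberellin-regulated MYB factor of cereal grains, went from 30.5 ± 1.05 to 2.54 ± 0.704 FPKM, and its call was lost after median-ratio scaling (log2 change -0.73). In the same libraries the 12 unannotated genes with the highest FPKM in any 1 library took 84.6% of the total against 53.8% at 15 DPA. Over all genes 8476 were called, 134 higher and 8342 lower, and after median-ratio scaling 3053, 780 higher and 2273 lower.

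**Figure D2:**
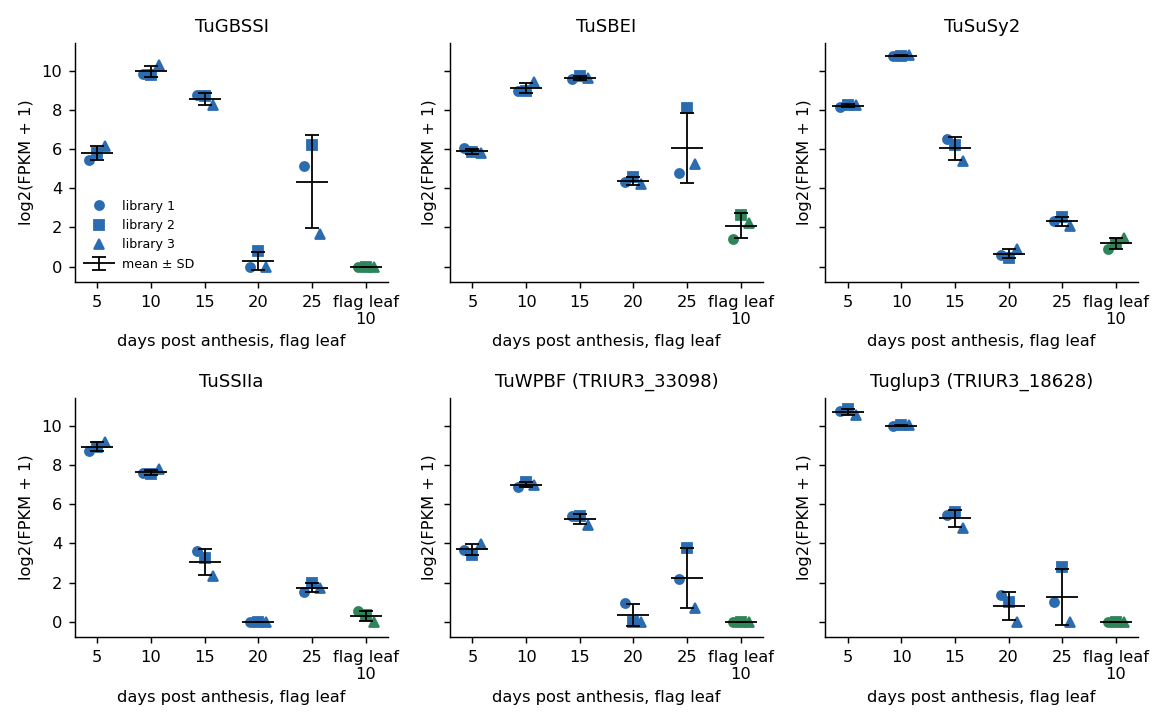
FPKM of 6 genes in each library on a scale of log2(FPKM + 1), with 1 point per library for the 5 endosperm stages and flag leaf and bars for the mean ± SD of 3 libraries. TuGBSSI is above 0 in 1 of the 3 libraries at 20 DPA and is listed at 0 in all 3 leaf libraries, and 25 DPA library 2 has the highest TuSBEI value of its group at 270.0 FPKM.

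At 25 against 20 DPA, the last interval of filling, the 25 DPA libraries were unlike one another. The 20 DPA libraries also ranked genes unlike one another. Their Spearman correlations over all genes were 0.612 to 0.624, against 0.697 to 0.845 among the 25 DPA libraries. Each 20 DPA library correlated more with 25 DPA library 2 (0.644 to 0.690). TuAGPL-cyto, the cytosolic large subunit of ADP-glucose pyrophosphorylase, had 28.7, 239 and 39.6 FPKM in the 25 DPA libraries against 2.90 ± 0.570 at 20 DPA (SD, n = 3), a log2 change of 4.10 (SE 0.68, limma adjusted p = 0.00711). TuGBSSI had 33.8, 73.5 and 2.17 FPKM against 0.253 ± 0.439, a log2 change of 4.06 that was not called without 25 DPA library 2. The bHLH gene TRIUR3_26625 had 10.9, 67.2 and 91.5 against 1.63 ± 1.42 FPKM, a log2 change of 4.21. Of the 28 starch genes 18 were called higher, 23 when adjusted over the list alone, with a median log2 change of 1.69 against 1.00 for all genes. Median-ratio scaling left 3 of these calls, the compared groups fitted alone left 0, and leaving out a 20 DPA library or 25 DPA library 2 or 3 left 1 to 10. Camera gave the starch genes an adjusted p of 0.00948, and adjusted p = 0.998 with an estimated correlation.

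The prolamins were not called at 25 against 20 DPA: limma gave 0 of 21, with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. Gli-γ-1 had 2586, 53309 and 11310 FPKM in the 25 DPA libraries against 9143 ± 2119 at 20 DPA (SD, n = 3). The median log2 change of the prolamins was 0.38 and the mean 0.46, whereas camera placed them below other genes (adjusted p = 0.00155, and adjusted p = 0.998 with an estimated correlation), since their median lay at -0.61 relative to all genes. After median-ratio scaling 13 of 21 were called lower, and without 25 DPA library 1, 6 were called higher. Over all genes 6876 were called, 6846 higher and 30 lower, against 1333 higher and 608 lower after median-ratio scaling. The compared groups fitted alone gave 29 calls. Leaving out 1 library gave 1369, 4233 and 2278 calls for the 20 DPA libraries in column order and 11499, 221 and 587 for those of 25 DPA.

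Across the whole period, 25 against 5 DPA, storage protein transcripts ended above their 5 DPA level and many genes of early endosperm ended low. The prolamin share of the 25 DPA libraries (0.382%, 12.1% and 1.99%) lay below the 21.1% ± 0.848 of 15 DPA. All 21 prolamin genes rose, 21 also when adjusted over the list alone and 21 after median-ratio scaling, with a median log2 change of 8.39 against -1.99 for all genes (camera adjusted p = 2.00e-57, and adjusted p = 0.143 with an estimated correlation). Tuglup3 (TRIUR3_18628) fell from 1688 ± 174 to 2.31 ± 3.17 FPKM (SD, n = 3), a log2 change of -9.45 (SE 0.66, limma adjusted p = 1.34e-08). TuSSIIa fell from 492 ± 77.7 to 2.37 ± 0.538 FPKM, the MADS-box gene TRIUR3_28216 from 732 ± 43.3 to 1.33 ± 1.02, and the B3 gene TRIUR3_21370 from 239 ± 30.5 to 0.153 ± 0.266. The YABBY gene TRIUR3_31693 stood at 187 ± 26.1 FPKM at 5 DPA and was listed at 0 in every 25 DPA library. In the other direction, the bZIP gene TRIUR3_31111 rose from 4.18 ± 1.25 FPKM to 18.1, 255 and 511 in the 25 DPA libraries, and the NAC gene TRIUR3_00447 from 0.79 ± 0.816 to 13.0, 575 and 122.

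Of the 28 starch genes, 23 fell from 5 to 25 DPA and 0 rose (0 at an unadjusted p under 0.05), 23 also when adjusted over the list alone, and after median-ratio scaling 13 fell and 2 rose. Their median log2 change was -2.88, and camera gave no call for them (adjusted p = 0.406). MADS-box genes fell in 25 of 31 cases and rose in 0 (0 at an unadjusted p under 0.05), 25 also when adjusted over the list alone and 17 after median-ratio scaling. Camera gave an adjusted p of 0.0396 for this family, and adjusted p = 0.998 with an estimated correlation. The median of the 83 genes abundant in flag leaf was 1.26, 3.75 and 1.52 FPKM in the 25 DPA libraries, against 529, 474 and 482 at 5 DPA. Over all genes 14683 were called, 700 higher and 13983 lower, and after median-ratio scaling 5817, 1558 higher and 4259 lower.

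Endosperm was set against flag leaf at 10 DPA to separate grain from vegetative expression. All 21 prolamin genes were higher in endosperm, 21 also when adjusted over the list alone. Gli-γ-1 stood at 52897 ± 375 FPKM against 1.31 ± 1.14 in leaf (SD, n = 3), a log2 difference of 14.65 (SE 0.45, limma adjusted p = 8.20e-07). TuSuSy2 stood at 1731 ± 27.5 against 1.3 ± 0.466 FPKM, and TuAGPS-cyto, the cytosolic small subunit of ADP-glucose pyrophosphorylase, at 533 ± 15.0 against 112 ± 61.5. TuGBSSI, TuWPBF (TRIUR3_33098), the NF-YC gene TRIUR3_29815 and the NAC genes TRIUR3_00447 and TRIUR3_01582 were listed at 0 in all 3 leaf libraries. Leaf was higher for the bZIP gene TRIUR3_12850, at 372 ± 86.1 against 0.677 ± 0.670 FPKM, a log2 difference of -7.85 (SE 0.41). The NAC gene TRIUR3_04286 stood at 204 ± 27.4 FPKM in leaf against 5.83 ± 3.45 in endosperm, and the NF-YC gene TRIUR3_09240 at 86.1 ± 13.1 against 1.96 ± 0.0862.

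Of the 28 starch genes 16 were higher in endosperm and 5 higher in leaf, with the same counts when adjusted over the list alone, and leaving out any 1 endosperm library left 10 higher. The count higher in leaf was 8 without leaf library 1 and 3 without leaf library 2. WRKY genes were lower in endosperm in 26 of 41 cases and higher in 2, again with the same counts when adjusted over the list alone, and leaving out a leaf library left 16, 8 or 9 lower and leaving out an endosperm library left 0 higher. Camera adjusted p values were 2.68e-19 for prolamins, 0.0148 for starch genes and 0.0016 for WRKY genes. With an estimated correlation the prolamins had adjusted p = 0.0967, and the starch and WRKY genes adjusted p = 0.998. Over all genes 8153 were called, 3628 higher and 4525 lower in endosperm, with a median log2 difference of -0.01. Median-ratio scaling gave 9134, 4811 higher and 4323 lower, with a median of 0.27. Without each endosperm library in turn, 5245, 5059 and 5144 were called.

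**Figure D3:**
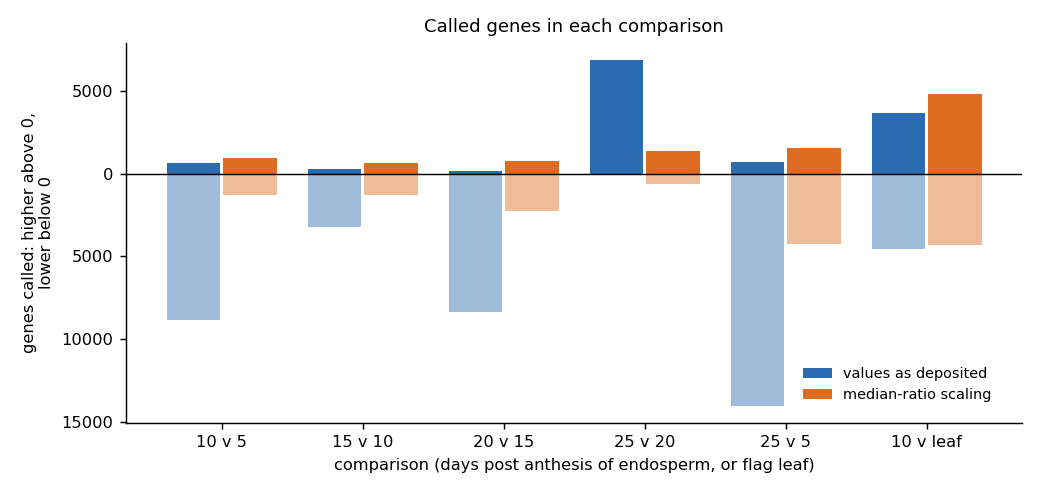
Number of genes called higher and lower in each comparison (bars from 0), from the values as deposited and after median-ratio scaling. At 10 against 5 DPA the genes called lower go from 8847 to 1303 with the scaling, and at 25 against 20 DPA those called higher go from 6846 to 1333.

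Over the 5 stages together, 17877 of 19418 genes passed the F-test, and 9119 after median-ratio scaling. Among the 17877, the mean FPKM was highest at 5 DPA for 15239 genes, at 10 DPA for 1138, at 15 DPA for 247, at 20 DPA for 80 and at 25 DPA for 1173. After median-ratio scaling these counts were 3955, 1931, 758, 1073 and 1402. The count at 25 DPA was 2236 without library 1 of that group and 588 without library 3. Libraries of the compared groups did not overlap for 78.8% of the genes tested at 10 against 5 DPA, 54.5% at 15 against 10, 58.0% at 20 against 15, 19.0% at 25 against 20, 72.6% at 25 against 5 and 59.1% for endosperm against leaf, where chance gives 10%. These shares rest on the values as deposited, so they include any shift common to most genes, which the 10% leaves out.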

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

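The fits of the compared groups alone, the scaling to the total outside the 12 most abundant genes and the fit without the 20 DPA libraries and 25 DPA library 1 were chosen after the data were seen, as were total FPKM scaling for the stage of the highest mean, 1 fit of 18 libraries for lists and stages, and shares without the 12 genes. No paired analysis was possible because the table's columns do not carry the numbers of the sample titles. Values below are reported again only where direction or side of the threshold changed, or a count moved by over 1.5 times. The cause was not tested, except that median-ratio scaling and fits of fewer libraries change by construction the general shift and the pooled spread. Of 5470 repeats of 243 gene values, 5133 kept their direction and side of the threshold, 229 lost a call, 98 gained one and 10 reversed. Of 612 repeats of 34 counts, list medians and shares, 541 kept theirs. Read depth is unknown, so its limit cannot be given.

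Median-ratio scaling gave 2233 calls at 10 against 5 DPA, 1930 at 15 against 10, 3053 at 20 against 15, 1941 at 25 against 20, 5817 at 25 against 5 and 9119 in the F-test, and highest means for 3955, 1931, 758 and 1073 genes at 5, 10, 15 and 20 DPA. It reversed TRIUR3_32855 (0.038, at 10 against 5 DPA), TRIUR3_31111 (0.31), TRIUR3_28409 (0.60) and TRIUR3_04238 (0.12, these at 20 against 15), Gli-γ-1 (-2.16) and TRIUR3_24172 (-2.18, at 25 against 20), and TRIUR3_23521 (1.31), TRIUR3_02784 (1.58), TRIUR3_33098 (0.73) and TRIUR3_16468 (0.14, at 25 against 5). List medians relative to all genes were -0.59 for prolamins at 20 against 15 DPA and 0.39 for starch genes at 25 against 20, no longer called by camera.

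A pseudocount of 0.1 gave 4030 calls at 10 against 5 DPA and 2090 at 15 against 10. A pseudocount of 5 gave 2171 calls at 15 against 10 DPA, 3888 at 20 against 15 and 3901 at 25 against 20. It made the starch fall at 15 against 10 DPA a camera call (-0.99), as did no filter (-1.06), 1 fit of 18 libraries (-0.85) and the groups alone (-0.66), and no filter did so at 25 against 5 (-1.44). At 25 against 20 DPA the prolamin median was 0.012 with a pseudocount of 5 and 0.12 with total FPKM scaling, both reversed, and -0.16 with no filter. The starch call at 25 against 20 DPA was lost with a pseudocount of 5 (0.49), a filter at 5 (0.31), total FPKM scaling (0.62) and the groups alone (0.12).

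The groups alone gave 6271 calls at 15 against 10 DPA and 29 at 25 against 20. Without the 20 DPA libraries and 25 DPA library 1, 15 against 10 DPA gave 6413 calls, and 156 and 2025 genes had their highest mean at 15 and 25 DPA. Highest means at 20 DPA numbered 41 with total FPKM scaling and 131 with scaling outside the 12 genes. Prolamin shares at 10, 15 and 20 DPA were 27.3%, 36.6% and 5.06% without the 10 most abundant genes of each library, and 32.8%, 45.7% and 6.69% without the 12. The former are not shares of all prolamins at 10 and 15 DPA, since Gli-γ-1 was among the genes left out there. The 12 include no prolamin.

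With an estimated correlation the list medians relative to all genes were unchanged and their calls lost: prolamins 12.74 (p = 0.109), 1.00, -2.67, -0.61, 10.38 (p = 0.143) and leaf 12.56 (p = 0.0967), and starch genes 0.50, -2.10, 0.70 and leaf 1.73 (p = 0.998 for those without a value).

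Leaving out 1 library in turn, calls ran from 6239 (without 5 DPA library 1) to 12354 at 10 against 5 DPA, 2327 to 6502 (without 25 DPA library 1) at 15 against 10, 5857 to 9995 at 20 against 15, 221 (without 25 DPA library 2) to 11499 (without 25 DPA library 1) at 25 against 20, 12406 to 15856 at 25 against 5, 5059 (without 10 DPA library 2) to 7725 against leaf, and 16311 to 18295 in the F-test. Highest means at 25 DPA ran from 588 (without 25 DPA library 3) to 2236 (without library 1). The starch median relative to all genes ran from -0.85 to -0.66 at 15 against 10 DPA, called by camera without 25 DPA library 2 (-0.78), and from 0.39 to 1.03 at 25 against 20, not called without 25 DPA library 1 (0.85) or 5 DPA library 2 or 3 (0.58, 0.59). The prolamin median at 25 against 20 DPA ran from -1.496 to -0.082, not called without 25 DPA library 1 (-0.25) or 3 (-0.082).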

Other observations

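The tests of explanations for the 12 abundant genes and for 25 DPA library 2, and the test of the flag leaf profile in all 5 DPA libraries, were chosen after the result was seen, while the counts of other splits of the samples and the test of leaf-like RNA in 5 DPA library 1 were planned before.

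Over the whole period from 5 to 25 DPA, every transcription factor family tested except EIL had more genes called lower than higher in the values as deposited, as had all genes together (13983 lower and 700 higher of 19418). In 8 of these families, called lower were 69 of 100 MYB, 37 of 60 bZIP, 21 of 30 NF-Y, 27 of 42 WRKY, 34 of 58 NAC, 36 of 43 B3 and 8 of 16 HSF genes, each with the same count when adjusted over the list alone, and 4 of 7 Dof genes, 3 when adjusted over the list alone. Called higher were 2 MYB, 5 bZIP, 4 WRKY, 8 NAC, 2 B3 and 1 HSF gene, and limma called 0 NF-Y and 0 Dof genes higher, with 0 at an unadjusted p under 0.05. After median-ratio scaling the lean was smaller, and absent for HSF: 19 MYB genes were lower and 9 higher, 12 bZIP lower and 10 higher, 5 NF-Y lower and 1 higher, 10 WRKY lower and 5 higher, 13 NAC lower and 8 higher, 14 B3 lower and 3 higher, 4 HSF lower and 4 higher, and 1 Dof lower and 0 higher. Without 5 DPA library 1, 16 WRKY genes were lower and 2 higher. The few genes called higher varied with single libraries: without 25 DPA library 1 they were 6 MYB, 3 NF-Y, 1 Dof and 4 B3, without 25 DPA library 2 they were 0 MYB and 1 WRKY, without 25 DPA library 3 they were 0 MYB, 3 bZIP and 2 WRKY, and without 5 DPA library 2 or 3 they were 0 or 1 MYB. Camera gave none of these 8 lists a call, with adjusted p values from 0.208 to 0.956. In the EIL family, named after its values were seen, TRIUR3_12419 and TRIUR3_20987 were called higher, TRIUR3_08597 lower and the other two of its 5 genes not at all, with the same counts when adjusted over the list alone, and 1 was higher and 0 lower after median-ratio scaling. Its median log2 change was -0.37, which lay 1.62 above that of all genes, with a camera adjusted p of 0.0101, and adjusted p = 0.998 with an estimated correlation. At 15 against 10 DPA, 2 of 16 HSF genes rose, 1 when adjusted over the list alone, and 14 were not called. Camera gave that family an adjusted p of 0.000935 there, and adjusted p = 0.998 with an estimated correlation.

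Genes abundant in flag leaf, chosen to be at least 10 times their 15 DPA mean there and above 0 in 5 DPA library 1, were measured in 5 DPA endosperm: the median of 83 such genes was 529, 474 and 482 FPKM in the 5 DPA libraries, against 1808, 2855 and 2729 in leaf. Some of the 83 genes held identical values, such as TRIUR3_13501 and TRIUR3_25901, and each is counted in the medians and ranges. The selection keeps the 15 DPA level of the 83 genes low, so 15 DPA is not compared with 5 DPA or leaf. One admixture of RNA with the flag leaf profile is argued against as the whole source, since the interquartile range of their log2 ratios to leaf was at least 1.59 in every 5 DPA library, against 0.577 to 0.900 between leaf libraries. The bound set beforehand, on 5 DPA library 1 alone (1.59 against 0.577 between leaf libraries 2 and 3), does not count against another green tissue, whose own profile was not analysed here, and the range between 5 DPA libraries was 0.213 to 0.634, not above that between leaf libraries. One admixture of such a tissue (per the labels, pericarp and seed coat were removed from the endosperm before extraction), expression of these genes in the young endosperm itself and several sources at once therefore cannot be told apart.

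The 12 unannotated genes held 83.2% to 86.1% of the FPKM at 20 DPA and 85.4% in 25 DPA library 1, with lower FPKM of most other genes. Low total depth is argued against, since the relative depth of these 4 libraries had a median of 0.786, inside the 0.599 to 1.06 of the other endosperm libraries. The estimate rests on only 108 to 173 weakly detected genes in each of these 4 libraries. It does not measure the depth left for genes outside the 12, which was not tested. One common factor from the 12 genes taking the counts does not account for every change. After scaling, 33.8% of 595 genes with a mean of at least 100 FPKM were still called between 20 and 15 DPA. Of these, 156 were lower and 45 higher. The test was chosen after a first one, on the spread of the changes, gave a marginal result. The test cannot show how much of the fall such a factor made, since scaled calls also came at 15 against 10 DPA (1930 over all genes). Days after anthesis alone are argued against at 25 DPA, where the SD of the share was 23.3 against at most 4.35 at the other endosperm stages. For 20 DPA the stage, RNA quality and library preparation stay open and were not tested.

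The prolamin share of 25 DPA library 2 was 12.1%, against 0.382% and 1.99% in the other libraries of its group. A 10 or 15 DPA library under another label is argued against by 95 genes that were late in 25 DPA library 3: in library 2 their median ratio to the highest 10 or 15 DPA library was 7.28, and 95 of 95 were above it, while library 1 had 0.626. RNA lying between 15 DPA and 25 DPA library 3 in one proportion was also tested. The 15 DPA proportion was 0.416 from prolamins (interquartile range 0.257) and 0.610 from late genes (0.147). The difference of 0.194 was just within the bound of 0.2 set for the test. Late genes were chosen for high values in library 3, which raises their estimate, so no conclusion is drawn from this difference. The 83 genes abundant in flag leaf argue against one proportion of that size. Their median was 24.4, 28.0 and 30.2 FPKM in the 15 DPA libraries, but 3.75 in 25 DPA library 2 and 1.52 in library 3. Other mixtures of samples, grains of an intermediate stage and slower development stay open.

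Other splits of the same libraries were counted for each fit. Every contrast of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split gave 9460 calls at 10 against 5 DPA and the highest other 7. These values were 3484 and 1 at 15 against 10, 8476 and 2 at 20 against 15, 14683 and 1 at 25 against 5, and 8153 and 0 for endosperm against leaf. At 25 against 20 DPA the real split gave 6876, and 2 of the 10 splits gave as many: setting 20 DPA libraries 1 and 3 with 25 DPA library 1 against the others gave 7375, which points to a structure of the samples. For the F-test, 1 of 100 regroupings of the 15 libraries, the real one, gave 17877, the smallest share that 100 allow. The median of the 99 others was 0, which argues against a random grouping as the source. The count does not set the stages apart from similar groupings, since the highest other gave 17621 although it mixed libraries of the later stages. That regrouping kept the 5 DPA libraries together and 25 DPA library 1 with 20 DPA libraries 1 and 3, again a structure of the samples.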
